A study of Mus musculus with 14 samples.

How the data were processed

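RNA of stably modified lines of MIN6, a mouse pancreatic beta-cell line that secretes insulin, was compared on 14 two-colour arrays. Per the labels, the lines were derived from cells at passage 24 and grown for 4 days in medium with 5 mM glucose before RNA was taken. The overexpressing lines were selected in 280 micrograms of G418 per ml and the knockdown lines in 400. Sir2OE1 and Sir2OE2 carried a retroviral Sirt1 gene and were each hybridised against pooled RNA of the empty-virus lines Neo1 and Neo2. Sir2KD1 and Sir2KD2 carried vectors for small interfering RNAs against Sirt1 and were each hybridised against the empty-vector line mU6pro. Channels were exchanged between arrays of a line. Slides of a line were not described as separate cultures, so p-values over arrays measure the spread between arrays, which may be technical. The ratio against 0 is the test, and it leaves out the spread of the control lines.

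The deposited values were log2 ratios of the channels, centred per probe. The array software, background correction, normalization and the direction of the ratio are not given in the sources used here. The values themselves showed the centring. Within each kind of perturbation the values of every complete probe summed to 0 over 6 of 7 arrays, with a largest deviation of 5.6e-08. The arrays left out of the sums were Sir2OE1 slide 2 and Sir2KD1 slide 2. Undoing the centring gave whole-number percent ratios for 100% of complete probes in each kind, at a relative tolerance of 1e-05. A factor common to all arrays of a probe and kind stays unknown. Median values per array ran from -0.0347 to 0.0165. With no intensities in the values used here, signal over background is unknown, and the number of arrays limits the precision.

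Arrays of a line with opposite channels correlated below 0 as deposited (mean r = -0.281 over 12 pairs), so by the rule set for this the values were taken as channel 2 over channel 1, and arrays with the line in channel 1 had their sign turned. Centring itself pushes such correlations below 0. With the centring undone the mean was 0.182, a sign that the rule would have read as values already turned. What the centring removed may be a channel offset of each probe, which makes arrays alike whatever their orientation. It may instead be the mean effect of the lines, if the deposited values were line over control already. The values do not tell these apart. The turn thus rests on the centred values alone and is an assumption. Of 77 probes with an absolute removed offset above 1 on the log2 scale in both kinds, 62 had offsets of the same sign, against 42.9 for independent signs. These offsets take the smallest whole-number percents of a probe. A factor shared by all its percents therefore lowers the offset, and probes affected in this way were not left out. Over all probes the offsets of the kinds had r = 0.0209. Whether both kinds hold the same channel on top is thus an assumption, for which those 77 probes are weak evidence. The overall sign was to be called likely only if Sirt1 was higher in overexpressing and lower in knockdown arrays. That condition was not met, so sizes are given with no settled direction. Plus and minus name the sides of the turned ratio, and whether plus means more RNA in the modified line is unknown. A change of the overall sign turns all 4 lines together, so statements of same side and opposite side hold either way, provided both kinds hold the same channel on top. Such statements also need the turn to be right. Had the values been line over control already, calls and sides would change, beyond the overall sign.

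Of 23232 probes, 16885 had 1 gene symbol, 143 had several and 6204 were not listed in the platform annotation, which dates from 2007. Symbols were updated through Entrez identifiers for 16205 probes, with the gene table of assembly GRCm38.p6 used for names only. Probes with several symbols were not named. Ins1, Ucp2 and Sirt7 had no singly named probe and were not analysed here. A probe was tested if it had values on at least 2 arrays of every line, which left 23230. A set of 329 probes in the overexpression arrays and 173 in the knockdown arrays carried, on at least 5 arrays, the same percent ratio (within 1 percentage point) as the most frequent exact set. Many of them belong to very abundant transcripts. They were treated as ratios with no information of their own, an inference from identical values and not from a scanner record, with limits set after the values were seen.

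Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 14 arrays, with a coefficient per line, and adjusted by the Benjamini-Hochberg method over probes at 0.05. The tests, gene lists, rule for named genes, rule for the ratio direction and most alternatives were fixed before the data were examined. The planned covariate was a single dye term. Because the values proved to be centred separately in each kind, the reported fit has a dye term for each kind, which is unaffected by that centring and leaves 8 residual degrees of freedom; the single term is given as an alternative. A probe is called in both lines when it passed in each with the same sign. Errors are standard errors of the line coefficients. The line is the independent replicate: the 4 line coefficients were tested again with limma, with 2 residual degrees of freedom. The gene lists were tested with camera on the line coefficients at a preset correlation of 0.01 and at an estimated correlation, and over 60 list tests. The lists cover NAD and sirtuins, beta-cell identity, insulin secretion, mitochondrial regulators, oxidative phosphorylation, glycolysis, p53, FoxO and NF-kappaB targets, interferon response, sterol and fatty acid synthesis, unfolded protein response, antioxidant defence, cell cycle, other islet endocrine cells, exocrine and duct cells, mesenchymal and immune cells, neuronal genes, cytosolic chaperones and the cytosolic ribosome. The ribosomal list took every symbol of Rpl or Rps and a number, and so also held a few S6 kinases.

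Genes were named by rule: Sirt1, the 10 genes per side and kind with the largest smaller-of-the-lines ratio among those called in both lines, those opposed in all 4 lines, those past the line-level difference (0 probes), up to 4 members per list, and Ins1, Ins2, Pdx1, Ucp2 and the sirtuins. In lists, a gene with several probes was represented by the probe with most values, and ties went to the first listed probe. With missing values in 5 of 23232 probes, nearly all these choices were ties and so followed the listed order. Tested on simulated data for both overexpressing lines over 23230 probes, centred in the same way, the fit recovered 0% of 50 probes changed by 0.5 on the log2 scale. It recovered 40% of 50 changed by 1 and 96% of 50 changed by 2, with 0 calls among 23030 unchanged probes. The simulated lines had no spread between lines and no deviation of the control RNA, so that 0 does not cover false calls from these sources. With the line as the replicate, the same simulation called 106 of the changed probes. That test is scaled by the spread between lines, which the simulation lacked, so this count does not measure its power in the real data. Chance agreement from the shared control RNA was simulated 20 times with unrelated lines. The first form of that simulation drew each probe's variance from other probes and overstated the variance between the lines; it was replaced by a form that keeps each probe's variance and matches the variance of the difference between the lines, but not their covariance. The change was made after the first results were seen, and results of both are given. Alternatives covered centring, scaling by the median absolute ratio, the dye term, probe filters, the variance prior, the threshold, the slide number as a block, probes averaged per gene, the probe that represents a list gene, the line as a random block and leaving out each array.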

Results

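Gene expression was profiled in 4 MIN6-derived lines on 14 two-colour arrays, each setting a line with altered Sirt1 against its own control RNA. Sirt1 is an NAD-dependent protein deacetylase. Sir2OE1 was measured on 3 arrays and Sir2OE2 on 4, against pooled Neo1 and Neo2 RNA. Sir2KD1 was measured on 3 arrays and Sir2KD2 on 4, against mU6pro RNA. The design asks which transcripts differ from control when Sirt1 is raised, when it is lowered, and whether those changes oppose each other. Ratios are given as plus or minus sides of the turned log2 ratio, since the overall direction is not settled. All calls and sides rest on that turn, which the values do not settle either.

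The Sirt1 probe did not pass the test in any line. Its log2 ratio was 0.08 ± 0.12 (SE, n = 3 arrays) in Sir2OE1, with limma adjusted p = 0.933, and -0.33 ± 0.10 (SE, n = 4) in Sir2OE2, with adjusted p = 0.131 and 4 of 4 arrays on the minus side. In Sir2KD1 it was -0.10 ± 0.12 (SE, n = 3), with adjusted p = 0.772, and in Sir2KD2 0.12 ± 0.10 (SE, n = 4), with adjusted p = 0.651 and 4 of 4 arrays on the plus side. Sir2OE2 and Sir2KD2 thus lay on opposite sides, while Sir2OE1 and Sir2KD1 lay on the other side from the second line of their kind. The probe's position relative to the transgene and to the small interfering RNA targets is not given in the sources used here, so the probe neither settles the direction nor checks the labels. The related genes Sirt2, Sirt3, Sirt4, Sirt5 and Sirt6 did not pass the test in any line either, and Sirt2 stayed between -0.07 and 0.05.

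**Figure D1:**
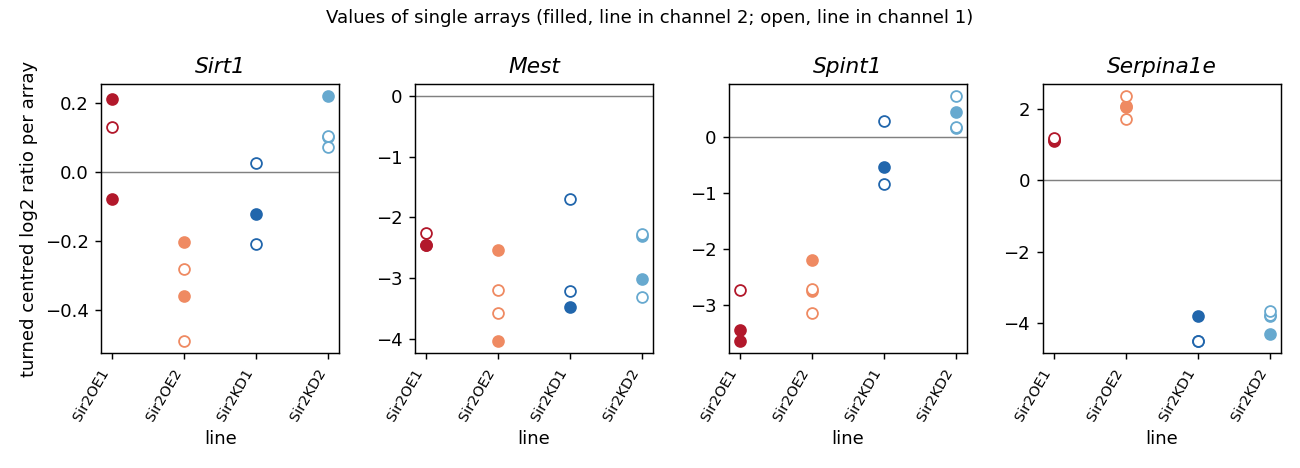
Turned, centred log2 ratio (vertical axis) of single arrays for Sirt1, Mest, Spint1 and Serpina1e in the 4 lines (horizontal axis). Filled points had the line in channel 2 and open points in channel 1; Mest lies on the minus side in all 4 lines and Serpina1e on opposite sides in the kinds of line.

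In the overexpressing lines, Esrp1, Spint1 and Mest on the minus side and Sod3, Uchl1 and Trpc6 on the plus side were among the genes furthest from the Neo control in both lines. On the minus side, the epithelial splicing regulator Esrp1 was at -3.45 ± 0.44 (SE, n = 3) in Sir2OE1 and -2.85 ± 0.37 (SE, n = 4) in Sir2OE2. The epithelial protease inhibitor Spint1 was at -3.27 ± 0.26 and -2.71 ± 0.22, and the tight junction protein Cldn7 at -2.01 ± 0.27 and -1.71 ± 0.22. In the knockdown lines Spint1 was not called at -0.40 and 0.37, and Cldn7 was called in Sir2KD2 alone, at 2.92. The imprinted gene Mest was at -2.38 ± 0.36 and -3.33 ± 0.31. On the plus side were the extracellular superoxide dismutase Sod3 (2.44 ± 0.15 and 4.13 ± 0.12), the neuronal ubiquitin hydrolase Uchl1 (2.45 ± 0.13 and 3.18 ± 0.11) and the cation channel Trpc6 (2.50 ± 0.25 and 2.57 ± 0.21). Folds of Sod3 were thus 5.43 and 17.6.

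The other leading minus-side genes were Rapgef2 at -2.30 and -2.64 in Sir2OE1 and Sir2OE2, the thioesterase Acot11 at -2.22 and -2.15, Tmed6 at -2.33 and -1.94, and the carbonic anhydrase Car15 at -2.16 and -1.54. Single probes named Ighm (-3.39 and -2.90) and Ighv6-6 (-2.67 and -2.13) were also among them, but the other 8 Ighm probes and the other 33 Ighv6-6 probes were not called, and neither was the other Acot11 probe. Further plus-side genes were 3110039M20Rik at 2.04 and 1.46, the serpins Serpina1e at 1.13 and 2.06 and Serpina1c at 0.95 and 1.82, and Rny1, an RNA of the Ro particle, at 1.05 and 1.44. Kcnmb4, a potassium channel subunit, was at 1.07 and 1.09, the ganglioside activator Gm2a at 1.13 and 1.00, and the contactin Cntn1 at 1.14 and 0.94, while the other Cntn1 probe lay on the same side at 0.96 and 0.67 and was not called. All 10 leading genes of each side had all 7 arrays on that side, and the largest adjusted p among the plus-side genes was 0.0453. Of these genes, Trpc6, Tmed6 and the Ighm probe were also called in Sir2KD1, at 1.56, -2.90 and -1.80, and not in Sir2KD2.

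Over all probes, limma called 247 in Sir2OE1 (109 plus, 138 minus) and 653 in Sir2OE2 (332 plus, 321 minus). Of these, 128 were called on the same side in both lines, 45 plus and 83 minus, where independent lists would share 1.56 and 1.91. Another 8 were called on opposite sides in the lines, 5 of them plus and 3 minus in Sir2OE2. With the line as the replicate, limma called 0 probes, and 1623 had an unadjusted p under 0.05 against 1162 by chance. With the line as a random block, 464 were called. The correlation within lines was 0.0194 in that fit, so it counted arrays almost as independent replicates and gave no line-level count. Without any 1 of its own arrays, the Sir2OE1 count was 86, 81 or 47 (slides 1 to 3) and the Sir2OE2 count 317, 339, 323 or 389 (slides 1 to 4). Without Sir2OE1 slide 3, the single array with that line in channel 1, 28 probes were called in both lines, and without slide 1 or 2 of Sir2OE1 56 each; without slides 1, 2 and 3 of Sir2OE2 the counts were 70, 71 and 68.

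In the knockdown lines, the alpha-1-antitrypsin family stood out on the minus side. Serpina1e was at -4.26 ± 0.19 (SE, n = 3) in Sir2KD1 and -3.89 ± 0.16 (SE, n = 4) in Sir2KD2, folds of 19.2 and 14.8. Serpina1a, Serpina1b, Serpina1c and Serpina1d lay between -4.97 and -2.92 in both lines; these paralogs are nearly identical and their probes may read each other's transcripts, so their single values are uncertain. The retinoblastoma-like protein Rbl2 was at -2.57 ± 0.18 and -2.60 ± 0.15, and Mest at -2.85 ± 0.36 and -2.72 ± 0.31. On the plus side, Fnbp1l was at 3.62 ± 0.31 and 3.31 ± 0.26 and the milk protein gene Csn3 at 2.77 ± 0.14 and 1.82 ± 0.12. The overexpressing lines were called on opposite sides for Csn3, at -0.87 in Sir2OE1 and 0.84 in Sir2OE2.

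Further minus-side genes were the oocyte homeobox gene Obox1 at -2.78 and -3.79 and the sulfotransferase Sult1d1 at -3.43 and -2.21. The G-protein regulator Rgs3 was at -2.11 and -2.15, although its other probe was not called. In the overexpressing lines the called Rgs3 probe passed on opposite sides, at 0.75 in Sir2OE1 and -0.615 in Sir2OE2. Further plus-side genes were Sod3 at 2.78 and 2.28, 3110039M20Rik at 1.83 and 2.00, Dcaf8l at 1.60 and 2.05, Snx31 at 1.67 and 1.46, Cmbl at 1.84 and 1.46, 4930430J02Rik at 1.45 and 2.47 and A030001D20Rik at 1.44 and 1.38. Some leading knockdown genes were also called on the same side in Sir2OE2: Fnbp1l at 1.58, Dcaf8l at 2.11, Cmbl at 1.00 and Sult1d1 at -1.78. Serpina1a, Serpina1b and Serpina1d were called on the opposite side there, at 1.90, 1.98 and 1.84. None of these was called in Sir2OE1. For Ucn3, a peptide of mature beta cells, the probes disagreed: one was at 2.86 and 2.62, and the other was not called at -0.95 and -0.40.

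Limma called 833 probes in Sir2KD1 (372 plus, 461 minus) and 312 in Sir2KD2 (140 plus, 172 minus). On the same side in both lines were 153, 57 plus and 96 minus, where independent lists would share 2.24 and 3.41, and 3 were called on opposite sides. Lines of a kind share a control RNA, so their lists are not independent. Without any 1 of its own arrays, the Sir2KD1 count was 523, 541 or 547 (slides 1 to 3) and the Sir2KD2 count 150, 179, 170 or 149 (slides 1 to 4), and 206 without Sir2OE2 slide 1. Without Sir2KD1 slide 1, 89 were called in both lines, and without slides 1 to 4 of Sir2KD2 83, 88, 96 and 84. With the line as the replicate, limma called 0 probes, with 2361 at an unadjusted p under 0.05 against 1162 by chance. With the line as a random block, 567 were called, again with arrays counted almost as independent. Simulated unrelated lines against one shared control gave on average 377 shared knockdown calls, 334 at the lowest, and 7.20 shared overexpression calls, 13 at the highest. In the first form of the simulation, which overstated the variance between lines, these were 829 and 232. Neither form matched both the variance and the covariance of the lines: for knockdown the matched form gave a covariance of 0.0661 between lines where the observed one was 0.03, and for overexpression 0.00694 where it was 0.0301, and the first form overstated the variance. What the shared control adds to either overlap is therefore unknown.

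Comparing the kinds, and taking the same channel as on top in both, 18 probes lay on the same side in all 4 lines and 7 on opposite sides, where independent lists would share 0.453 and 0.390. Same-side genes on the minus side included Mest, the glucose transporter Slc2a2 (-0.90 ± 0.16 and -1.50 ± 0.13 in the overexpressing lines, -2.08 ± 0.16 and -0.89 ± 0.13 in the knockdown lines) and the cyclin Ccnd2, whose 2 probes were both called. On the plus side were Sod3, Uchl1, 3110039M20Rik and 4 probes with no gene name. The opposed genes were Car15 (-2.16 and -1.54 against 1.34 and 1.16), the transporter Abcc3 (-1.41 and -1.02 against 1.24 and 1.13), the calpain Capn9 (-1.38 and -0.64 against 1.00 and 1.01), Serpina1c and Serpina1e, with 2 probes that have no gene name. Without Sir2OE1 slide 1 or slide 3, 4 and 2 opposed probes were called, and without slides 1, 2 and 3 of Sir2OE2 4, 4 and 3. Across probes, which are not independent replicates, the mean overexpression and knockdown values had Pearson r = 0.0917 and Spearman rho = 0.0803. Between single lines r was 0.0468 for Sir2OE1 with Sir2KD1, -0.0252 for Sir2OE1 with Sir2KD2, 0.125 for Sir2OE2 with Sir2KD1 and 0.0572 for Sir2OE2 with Sir2KD2. Within a kind, where lines share a control RNA, r was 0.247 for the overexpressing lines and 0.183 for the knockdown lines. If the knockdown ratios had the other channel on top, 7 probes would lie on the same side and 18 on opposite sides, and r would be -0.0917. With the line as the replicate, limma called 0 probes for overexpression minus knockdown, with 1822 at an unadjusted p under 0.05. With the line as a random block, 332 were called, again with arrays counted almost as independent.

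**Figure D2:**
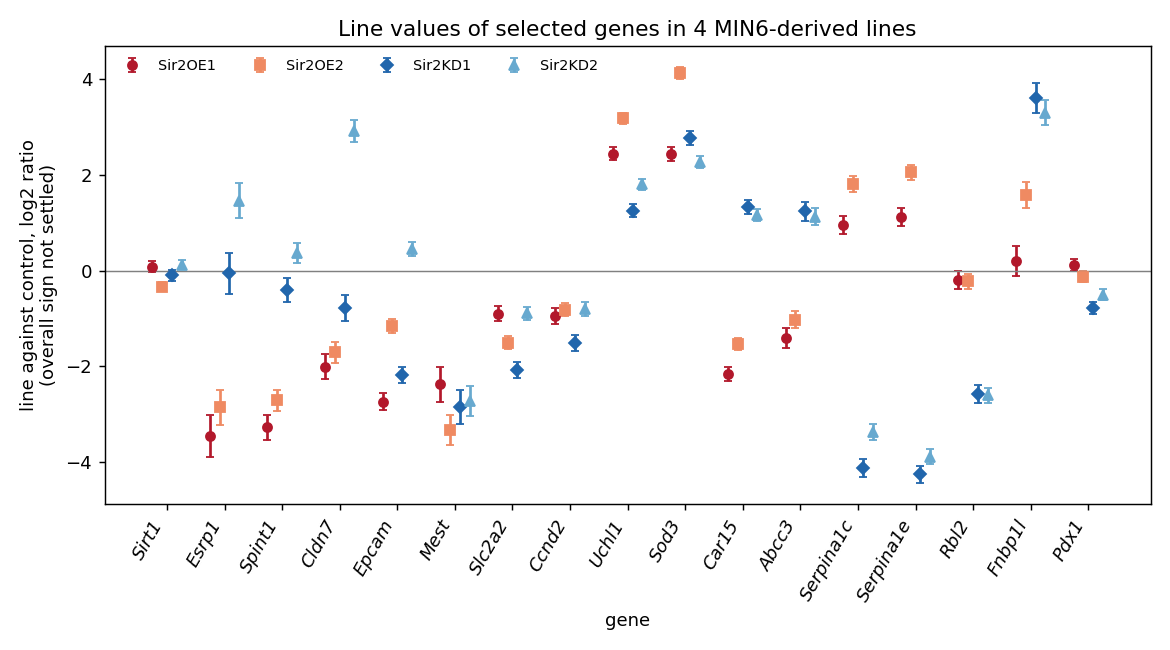
Line coefficients with standard errors as log2 ratios against control (vertical axis) for 17 genes (horizontal axis), with the sign common to all lines not settled. Mest, Slc2a2 and Ccnd2 lie below 0 in all 4 lines, Uchl1 and Sod3 above, and Car15, Abcc3 and the serpins on opposite sides in the kinds.

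Of the beta-cell identity genes, Slc2a2, Hnf4a and Isl1 were called on the minus side in both knockdown lines. Of 15 measured members, each read from 1 probe, 3 were called on the minus side in both lines and 0 on the plus side, and 4 were called on the minus side adjusted over the list alone. Those called among all probes were Slc2a2, the hepatocyte factor Hnf4a (-1.17 ± 0.21 and -0.97 ± 0.18) and the homeobox factor Isl1 (-0.78 ± 0.13 and -0.59 ± 0.11), while the other Hnf4a probe was not called. Pdx1, a master factor of beta cells, was at -0.77 ± 0.13 with adjusted p = 0.00796 in Sir2KD1 and -0.50 ± 0.11 with adjusted p = 0.0534 in Sir2KD2, with 7 of 7 arrays on that side. Camera gave the list an adjusted p = 0.00445 at the preset correlation and adjusted p = 0.914 with an estimated correlation. The call depended on the probes taken: with the last probe of each gene that has several, which changed 4 members and gave Ucn3 its plus-side probe (2.86 and 2.62) in place of the other (-0.95 and -0.40), 1 member was called plus and 2 minus, with camera adjusted p = 0.56. The homeobox factor Nkx6-1 was not called, at 0.37 and 0.25 with 7 of 7 arrays on the plus side. Slc2a2 alone was called in both overexpressing lines, and the list's adjusted p was 0.534. Isl1 was called in Sir2OE1 only, at 0.70, and the factor Neurod1 in Sir2OE2 only, at -0.50. With the same channel on top in both kinds, overexpression minus knockdown had an adjusted p = 0.188 for the list (p = 0.0157, and 0.000608 with the knockdown ratios turned, both unadjusted), 0.00797 on the 14 arrays, 0.0145 without members that share the fixed ratio and 0.74 with the last probe of each gene; with an estimated correlation the adjusted p was 0.914. Ins2 was not called in any line, with values between -0.44 and -0.07, and shared the fixed ratio in the overexpression arrays.

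Among genes of insulin secretion, 2 of 34 were called on the plus side in both overexpressing lines, and 3 adjusted over the list alone. The 2 were the prohormone convertase Pcsk1 (0.78 ± 0.13 and 0.78 ± 0.11) and the vesicle GTPase Rab3a (0.67 ± 0.13 and 0.66 ± 0.11). For knockdown 0 were called in both lines, and Pcsk1 was called in Sir2KD2 only, at 0.76. Of 27 mitochondrial regulators, the uncoupling protein Ucp1 was called on the minus side in both overexpressing lines (-1.35 ± 0.15 and -0.58 ± 0.13), and 2 adjusted over the list alone. For knockdown Ucp1 lay on the plus side, at 0.44 in Sir2KD1 and 0.62 in Sir2KD2, and was called in Sir2KD2 only. Of 18 p53 targets, the kinase Plk2 was called in both overexpressing lines, at -0.78 and -0.83. The list's median for overexpression was 0.24, on the plus side. Its camera adjusted p was 0.0638 on the line values, 0.012 on the 14 arrays and 0.914 with an estimated correlation. Adjusted over the list alone, 1 plus-side and 1 minus-side member passed in each kind. Of 46 cell cycle genes, Ccnd2 alone was called in both lines of each kind, among all probes and adjusted over the list alone. Another 5 were called in 1 overexpressing line only. Of 25 exocrine and duct genes, Epcam (-2.74 and -1.15) and the keratin Krt19 (-0.58 and -0.69) were called on the minus side in the overexpressing lines, and Krt7 on the plus side in the knockdown lines (0.93 and 1.29). Adjusted over the list alone, these were 2 on the minus side for overexpression and, for knockdown, 1 on the plus side and 2 on the minus side.

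Of 24 neuronal genes, Uchl1 and Cntn1 were called on the plus side and the decarboxylase Ddc on the minus side (-0.85 and -0.79) in the overexpressing lines, and Uchl1 (1.26 and 1.81) and Stmn2 (1.77 and 1.10) on the plus side in the knockdown lines. Stmn2 was also called in Sir2OE2, at 2.32, and not in Sir2OE1, at 0.47. Ddc was also called in Sir2KD1, at -1.25, and not in Sir2KD2, at 0.42. Adjusted over the list alone, 3 plus and 2 minus members passed for overexpression and 2 plus and 1 minus for knockdown. Of 13 cytosolic chaperones, Hspb8 was called in the overexpressing lines at 1.06 and 0.80, and 1 member passed on the plus side in each kind adjusted over the list alone. Hspb8 was also called in Sir2KD1, at 2.78, and not in Sir2KD2, at 0.72. In both knockdown lines 1 of 19 FoxO targets, Rbl2, and 1 of 29 unfolded protein response genes, Asns (0.61 and 0.67), were called. The same numbers passed adjusted over the list alone. The lists of NAD and sirtuin genes, oxidative phosphorylation, glycolysis, NF-kappaB targets, interferon response, sterol and fatty acid synthesis, antioxidant defence, other islet endocrine cells and mesenchymal and immune cells had 0 members called in both lines of either kind. Adjusted over the list alone, 1 glycolysis gene on the plus side and 1 sterol gene on the minus side passed for overexpression, and 1 gene of other islet cells on the minus side for knockdown. Lists with 0 members called in both lines, apart from the ribosome, had medians between -0.16 and 0.09 for overexpression and between -0.12 and 0.15 for knockdown. The lowest camera adjusted p among them was 0.246. In the overexpression arrays 22 of 53 oxidative phosphorylation members and 5 of 22 antioxidant members shared the fixed ratio. In the knockdown arrays 7 and 1 did. Such ratios were treated as holding no information, so 0 calls among these members say little. Without them, the oxidative phosphorylation list moved from the minus to the plus side for overexpression, with camera adjusted p = 0.787. Median and mean differed in sign for beta-cell identity in overexpression (0.0016 and -0.11), and in knockdown for FoxO targets (0.09 and -0.06), neuronal genes (-0.07 and 3.41e-05) and mesenchymal and immune cells (0.03 and -0.02); camera went with the mean for beta-cell identity and for mesenchymal and immune cells, and with the median for the others. The ribosomal list had 0 of 71 members called in both lines of a kind, and 1 called in 1 line only in each kind. Yet camera gave it an adjusted p = 1.5e-08 on the minus side in the overexpressing lines and adjusted p = 0.914 with an estimated correlation. Of its members, 47 shared the fixed ratio there, and without them its median was 0.01 with adjusted p = 1.00. Overexpression minus knockdown gave the ribosomal list an adjusted p = 4.56e-05, adjusted p = 0.914 with an estimated correlation, and 0.902 without such members.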

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

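The tests of the ribosomal list, the paralogs and the balance of same-side and opposite-side genes were chosen after those results were seen.

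Within a line of 4 arrays, 2 of 65 values of Sirt1 and of named genes called in both lines of the kind had an array far from the others, against 3.25 expected by chance. Gm2a was at 1.19 on Sir2OE2 slide 4 with the others from 0.90 to 0.95, and the Ighv6-6 probe at -1.66 on slide 2 with the others from -2.32 to -2.25. By a limma test of the difference itself, with the same channel on top in both kinds, 75 probes differed between Sir2OE1 and Sir2OE2, 160 between Sir2KD1 and Sir2KD2, and 617 between overexpression and knockdown over arrays, the last being 1160 with the knockdown ratios turned the other way. Of 175 probes of named genes, 9 differed between the overexpressing lines and 11 between the knockdown lines, with the lines on opposite sides in 6 and 7 of them. Sir2OE1 minus Sir2OE2 was -1.69 for Sod3 (adjusted p = 0.00653), -1.59 for Epcam, -1.72 for Csn3, -1.85 for Stmn2, -1.27 for a Ucn3 probe, -1.33 for the lactate dehydrogenase Ldha, 1.37 for Rgs3, 1.21 for the sterol enzyme Msmo1 and 2.70 for Sult1d1. Sir2KD1 minus Sir2KD2 was -3.70 for Cldn7 (adjusted p = 0.000896), -2.64 for Epcam (adjusted p = 0.000606), -3.05 for an Ighm probe, -2.23 for Tmed6, -2.96 for the glutathione peroxidase Gpx2, -1.66 for Ddc, -1.18 for Slc2a2, -1.05 for Msmo1, 0.95 for Csn3, 1.68 for Phlda3 and 2.06 for Hspb8. The largest adjusted p among these was 0.044.

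The ribosomal list shifted in the overexpressing lines through probes that held one shared ratio on each array, such as 255% on Sir2OE2 slide 4. Without the 47 such members its camera adjusted p was 1.00, and with them it was 0.914 at an estimated correlation. Spots at the scanner's ceiling in both channels may be the source, which the values cannot show directly. No separate biological explanation was tested.

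Lines made to raise and to lower Sirt1 had 18 probes on the same side in all 4 lines and 7 on opposite sides, or 7 and 18 if the knockdown ratios have the other channel on top. Against a channel offset, 18 of 18 kept 1 side in both channel orientations of both kinds after the centring was undone, although calls from a fit with dye terms favour that outcome. Genes that vary between clones in either direction would give a same-side share of 0.538, and 17 same-side against 6 opposite-side genes or unnamed probes, with paralogs counted as 1, gave an exact two-sided binomial p = 0.0604 (0.0347 against equal numbers). Such variation and a change common to the kinds cannot be told apart, because the counts are small, genes are not independent and the channel on top is assumed. Selection or drift common to the modified lines and the control lines' own state stay open as untested, as does an effect of Sirt1.

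The 5 Serpina1 paralogs moved together in the knockdown lines, with means from -4.21 to -3.13, a range of 1.08 against a mean standard error of 0.203. In the overexpressing lines the means ran from 1.38 to 1.60, a range of 0.212 against a mean standard error of 0.203. These errors are those of single lines, and means over lines have smaller ones. The overexpression range lay within the limit set for probes reading one transcript mix, and the knockdown range lay outside it. Cross-hybridisation and a joint change of the genes cannot be told apart, because the probe sequences are not used here.

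Other splits of the 7 arrays of a kind by channel orientation, 4 against 3, were refitted. In each kind, 1 of 34 splits, the real one, gave as many probes called in both lines: 128 against at most 8 for overexpression and 153 against at most 3 for knockdown. The labels give the orientation, so its chance assignment was not a live question. If the turn is right, a wrong split turns line values the wrong way and moves them into the residuals, so the real split was bound to lead. The counts show that values differ with the channel orientation. A channel offset of each probe, in values that were line over control already, could give this too. The counts therefore do not settle the turn, and say nothing on clone variation or the shared control. The share is the smallest the splits allow.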

How the results depend on the processing

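The reported dye term for each kind replaced the planned single term after seeing the data. Undoing the centring, leaving out control or fixed-ratio probes, the last probe of list genes and turning the knockdown ratios were chosen after seeing the data, as was the random block for the line-level overexpression and knockdown counts. Counts are for Sir2OE1, Sir2OE2, Sir2KD1, Sir2KD2, both overexpressing lines, both knockdown lines and the opposed probes, where they moved by over 1.5 times. With no dye term they were 628, 1190, 1867, 810, 263, 332 and 16. With an absolute log2 ratio of at least 1 they were 127, 265, 447, 151, 44, 70 and 4. With the slide number as a replicate block they were 79, 380, 300, 160, 47, 70 and 3; slide numbers did not pair the arrays, since residuals of same-numbered arrays of different lines had a mean r of -0.0658 over 19 pairs, and 1 pair was above 0.1. With the planned single dye term Sir2OE1 had 406, Sir2KD1 1315, Sir2KD2 541, both overexpressing lines 195 and the opposed probes 12. With the centring undone and that term the first 6 counts were 149, 428, 454, 183, 80 and 97. Scaling gave 1021 for Sir2OE2 and 401 for Sir2KD1, of which 136 were plus. The causes were not tested, except that a stricter threshold calls fewer probes by construction.

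Treating the line as a random block gave 464 probes for overexpression, 567 for knockdown and 332 for the difference, against 0 with the line as the replicate. The correlation within lines was 0.0194, at which arrays count almost as independent replicates, so these are not line-level counts. The correlation of the kinds was -0.0252 for Sir2OE1 with Sir2KD2. With the knockdown ratios turned the other way it was -0.0917, the opposed probes were 18, and 1 probe differed between the kinds with the line as the replicate, which has no gene name. Lists past camera numbered 1 for overexpression, knockdown and the difference; they were 0 with the estimated correlation, 2, 1 and 2 on the 14 arrays (with p53 targets added for overexpression and beta-cell identity for the difference), 0 for overexpression without fixed-ratio members, and 0 for knockdown with the last probe of each gene.

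Leaving out 1 array gave 47 to 222 probes in Sir2OE1, 317 to 675 in Sir2OE2, 523 to 835 in Sir2KD1, 149 to 325 in Sir2KD2, 28 to 120 in both overexpressing lines, 83 to 146 in both knockdown lines and 2 to 7 opposed probes. Each array of a line moved that line's count by over 1.5 times: slides 1 to 3 of Sir2OE1 left 86, 81 and 47, slides 1 to 4 of Sir2OE2 317, 339, 323 and 389, slides 1 to 3 of Sir2KD1 523, 541 and 547, and slides 1 to 4 of Sir2KD2 150, 179, 170 and 149. Without Sir2OE2 slide 1 the Sir2KD2 count was 206. Shared calls without single arrays: both overexpressing lines 56, 56 and 28 without Sir2OE1 slides 1 to 3 and 70, 71 and 68 without Sir2OE2 slides 1 to 3; both knockdown lines 89 without Sir2KD1 slide 1 and 83, 88, 96 and 84 without Sir2KD2 slides 1 to 4; opposed probes 4 and 2 without Sir2OE1 slides 1 and 3 and 4, 4 and 3 without Sir2OE2 slides 1 to 3. Of the values of named genes under the alternatives run, 8379 kept their side and call, 229 lost the call, 37 gained one, 101 values without a call changed sign and 0 called values did; without Sir2OE1 slide 3 alone, 24 lost the call and 22 without a call changed sign. Most of these values had no call to lose: an alternative held up to 350 values, of which fewer than 65 were called in the reported fit. Most of the 8379 thus kept the absence of a call, and the lost calls weigh against far fewer called values. The number of arrays limits the depth of these statements, as signal over background is unknown.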

Other observations

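The epithelial list was written after the values of Esrp1, Spint1, Cldn7 and Epcam were seen and without them, and its test was set before its result was seen.

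In the overexpressing lines the leading minus-side genes Esrp1, Spint1 and Cldn7, and Epcam, which was called but not among the leading genes, belong to epithelial cells. In single knockdown lines Epcam was also called at -2.18 in Sir2KD1 and Cldn7 at 2.92 in Sir2KD2. A hypothesis is that a wider epithelial program moved with them. Of 40 other epithelial genes, some of cell junctions and some of other functions, 36 were measured. Their median mean log2 ratio was -0.17, on the side of the genes above. It lay at percentile 100 among 10000 random gene lists of that size. The splicing regulator Esrp2 was at -1.10 and -1.25 in Sir2OE1 and Sir2OE2, desmoplakin Dsp at -2.12 and -1.85, Ap1m2 at -1.23 and -1.06 and Cldn3 at -0.62 and -0.45; of the 36, 2 were called in both lines, Ap1m2 and Cldn3. These examples were chosen after their values were seen. In the knockdown lines, tested after the result for overexpression was seen, the median was -0.03 at percentile 82.7 toward the minus side, and 1 of 36 was called in both lines, Ocln at -1.51 and -1.27; the difference between the kinds was not tested. The random lists were not matched on expression, which is unknown here, and genes of 1 program vary together, so the percentile overstates the evidence. The result is consistent with a shift of epithelial genes between these lines and the Neo pool, and it does not tell whether Sirt1 or the choice of clones brought it.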
